A study of Homo sapiens with 21 samples.

How the data were processed

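RNA had been sequenced in 21 libraries of 3 human medulloblastoma cell lines. Per the labels, total RNA was purified on columns, polyadenylated RNA was made into libraries with a kit that keeps no record of the strand, and single reads were taken on a HiSeq instrument. The authors aligned the reads to the human genome, build GRCh37, with HISAT2, and assigned them to genes with HTSeq; the labels give no version of either. The deposited values are raw counts of reads per gene, 1 file per library, and no normalised values were used here. Each file held 57820 gene identifiers followed by the classes of reads assigned to no gene.

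The name table that accompanied the annotation matched 51996 of the identifiers to a symbol, and all tables combined matched 52338. The 47 identifiers of the second copy of the pseudoautosomal region were dropped from naming. Gene types and 3' untranslated regions came from GENCODE release 29, which is built on GRCh38, so its coordinates are those of the later build. A 3' untranslated region was found for 18698 genes.

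The counts assigned to genes ranged from 1956353 to 18061910 per library, with a median of 7792825. The untreated D283 libraries held 7792825 to 11124512 and the untreated D425 libraries 9586927 to 18061910. The drug libraries held 4934463 to 5663032 in D283 and 3529904 to 3987444 in D425. In HD-MB03 the parental library held 2083297, the vector library 1956353, and the miR-592 libraries 12735937 and 13970677. Of all reads listed, 20.2% to 49.5% were assigned to no gene, being unaligned, not unique, ambiguous or outside genes; those outside genes made up 4.32% to 11.0%. Between 16606 and 23284 genes had at least 1 count. Libraries of the same population differed by more than counting error, so none repeated another's reads.

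Groups were taken from the labels, and 17 groups were formed by line, population and drug. In the 13 untreated libraries, miR-592 libraries were compared with parental and vector libraries of the same line, in a model with a level for each line and each line's response. The average of the 3 responses, each response, and the difference between the responses were tested. Vector and parental libraries were compared with line as a block. In the 12 libraries of D283 and D425 that covered the drugs, each drug was compared with the untreated library of the same population, with population as a block. The difference in drug response between miR-592 and vector cells, and miR-592 against vector cells within each drug state, were tested in models on the same libraries.

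Counts were scaled with trimmed means of M values and tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3. Genes passed a filter of 10 counts scaled to library size in enough libraries and 15 counts in all. P-values were adjusted over all genes tested by the method of Benjamini and Hochberg, and a gene was called below 0.05. The standard error (SE) printed beside a log2 fold change is the size of the change divided by the root of its F statistic. Levels are CPM, the counts scaled to a common library size. All p-values of single genes reflect the spread among these libraries of 3 cell lines. Replicates were separate libraries of a line, and no donors were sampled. Over the lines, the spread was that among libraries within each line's groups. Differences in response between lines did not enter it, so a small p there does not mean that the lines responded alike. In the comparisons of drugs, each population had 1 library per state, so the spread was that between populations.

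Gene lists were written before the data were examined: candidate miR-592 targets; neuronal differentiation; synapse and excitability; neurogenic transcription factors; Group 4 medulloblastoma; Group 3 and photoreceptor; SHH and WNT medulloblastoma; neural progenitor; ERK pathway output; sterol and lipid synthesis; ATF4 and amino acid synthesis; glycolysis and hypoxia; lysosome and autophagy; ribosome biogenesis; ribosomal proteins and translation; cell cycle; p53 targets; interferon response; glial, mesenchymal, and endothelial and blood markers; housekeeping; and the miR-592 identity genes MIR592 and GRM8. Of the 23 lists, 22 were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. The symbols NEFL, BOP1, DDX58 and PECAM1 matched no identifier. TUBB3, EOMES, KCNA1 and NGFR did not pass the filter.

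The rule for naming genes was also written before the data were examined. Among protein-coding genes called with at least 2 CPM in the higher group and the same sign in every line or population, it took the 6 largest rises and 6 largest falls, or 3 and 3 within a line and for the difference in drug response. From each list it took up to 4 called members with the smallest p, or the 2 with the smallest p where none was called. MIR592, GRM8, DEPTOR, MYC, OTX2, EOMES, KCNA1, NRL, DUSP6, SPRY4, EGR1, HMGCS1, ASNS, MKI67, TUBB3, NEFL, STMN2 and DCX were always included where tested. The text gives those that carry a comparison and summarises the others. A few genes that the rule names are not reported here.

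Where every library of a group held 0 counts of a gene, its fold is a lower bound against a floor of 3 counts over the group. Where a group held 1 to 3 counts, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only, since reads were not marked by molecule.

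Sites for miR-592 were sought in the longest 3' untranslated region of each gene as the 7-mer TGACACA, which pairs with bases 2 to 8 of the mature microRNA, and as the 8-mer TGACACAA. Median log2 fold changes of genes with and without a site were compared by 100000 two-sided permutations of the genes within 10 classes of region length, and by 10000 for each alternative. The p-values were adjusted over the 4 comparisons, all lines and each line. Permuted differences were not centred on 0, because longer regions hold more sites, so differences are read against the mean of the permuted ones. Genes restricted to a line were those with at least 20 CPM in every untreated library of D283 or D425 and at most 0.5 CPM in each untreated library of the other line. GC content per gene was corrected within each library with a spline of 6 degrees of freedom.

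The tests were tried on simulated data with 200 changed genes, 100 at a log2 change of 1 and 100 at 2. The comparison over the lines recovered 67% and 92% of them, D283 42% and 91%, D425 18% and 87%, and HD-MB03 32% and 67%. The comparison of vector with parental cells recovered 49% and 89%, rapamycin 29% and 77%, and U0126 32% and 82%. The difference in rapamycin response recovered 0% and 1%, and miR-592 against vector without drug 1% and 10%. Of the simulated calls, 0% to 17.9% were false. The planted list was found by camera in each of these comparisons.

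Alternatives were DESeq2 1.42.0 size factors, its test, no filter, vector or parental controls alone, each line fitted on its own or left out, subsets of lines or populations, no population block, and each library left out in turn. Added after the data were seen were the GC correction, thinning of the HD-MB03 miR-592 libraries, leaving out the D425 miR-592 population given drugs, and the comparisons of miR-592 with vector within drug states. The tests with genes restricted to a line were not planned beforehand either, since they address a feature seen in the data. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for file reading, site counts and plots. No library was left out of the comparisons its group belonged to. Splicing, variants and the strand of origin were left out, because the files hold counts per gene only.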

Results

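Gene expression was measured by RNA sequencing in D283, D425 and HD-MB03, 3 lines grown from Group 3 medulloblastoma, a malignant tumour of the cerebellum in children. Each line was present as parental cells, as cells carrying an empty lentiviral vector, and as cells in which doxycycline switches on miR-592, a microRNA whose gene lies within the glutamate receptor gene GRM8. Per the labels, every culture received doxycycline at 1 µg/ml for 72 h. Untreated D283 had 2 parental, 1 vector and 2 miR-592 libraries; D425 and HD-MB03 each had 1 parental, 1 vector and 2 miR-592 libraries. The vector population and the miR-592 population number 2 of D283 and of D425 were also given rapamycin, an inhibitor of mTOR, or U0126, an inhibitor of the MEK kinases upstream of ERK, with 1 library for each of these 8 states. The labels give neither the dose nor the duration of the drugs, and mark the controls of D425 and HD-MB03 as re-used. Counts in genes ranged from 1956353 to 18061910 per library; the HD-MB03 controls were the shallowest, at 2083297 and 1956353.

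The induction of miR-592 itself was read from MIR592, on chromosome 7 at 127058088 to 127058184 of GRCh38, minus strand. In D283 it stood at 4089 and 2206 CPM in the miR-592 libraries against 1 count over the 3 controls. The D425 miR-592 libraries held 909 and 799.7 CPM, and the HD-MB03 ones 225 and 256 CPM. Controls of D425 held 3 counts and those of HD-MB03 none, so the level in HD-MB03 was at least 286-fold higher. The ratio in D425 was 8187 (95% counting interval 2801 to 39700). Over the lines the adjusted p was 3.54e-09 in edgeR, and the level was higher in all 6 miR-592 libraries. Under drugs, the D283 population held 502 CPM with rapamycin and 503 with U0126, and the D425 population 377 and 449.6 CPM; no vector library given a drug held a count. These reads measure the transcript around the microRNA, not the mature form. GRM8, the host gene, stood at 2.81 CPM in D283 controls and 3.73 in D283 miR-592 cells (adjusted p = 0.773), and held 2 counts over the 8 untreated libraries of D425 and HD-MB03.

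**Figure D1:**
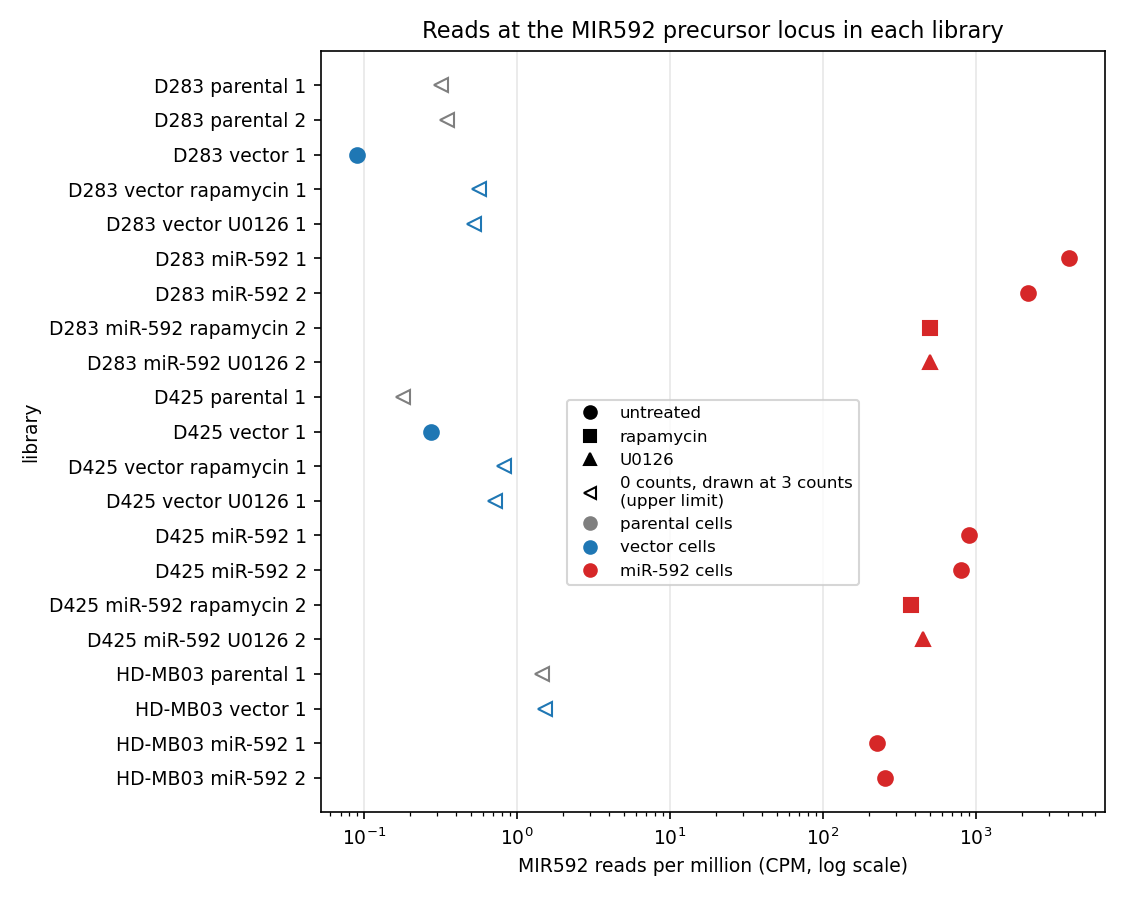
MIR592 level in each library, in CPM on a log axis, by line, population and drug, with libraries of 0 counts drawn at the floor of 3 counts. Every miR-592 library sits above every parental and vector library.

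The comparison of miR-592 with control cells over the 3 lines asks what miR-592 does to expression on average in these lines. The series names neuronal differentiation of the kind seen in Group 4 tumours as its interest. Some of the called rises named here were genes of vesicle release, a grouping that was not tested as a list. UNC13A, which primes synaptic vesicles for fusion, rose by 3.15 ± 0.49 on the log2 scale (SE; 7 controls, 6 miR-592 libraries; adjusted p = 0.0045), with 2.50 in D283, 4.47 in D425 and 2.50 in HD-MB03. SNAP25, a membrane protein of vesicle fusion, rose by 2.71 ± 0.35 (adjusted p = 0.00242). CHGB and SCG3, proteins of dense-core secretory granules, rose by 2.95 ± 0.55 and 2.56 ± 0.42 (adjusted p = 0.00947 and 0.00599). NEFM, the medium neurofilament of axons, rose by 2.01 ± 0.33 (adjusted p = 0.00628), although HD-MB03 controls held 3 counts of it and the ratio there was 5.43 (1.81 to 26.8). SYT4, a vesicle protein of the synaptotagmin family, was at least 13.9-fold higher in HD-MB03, and its ratio in D425 was 9.62 (1.24 to 434). NHLH1, a transcription factor of young neurons, rose by 1.51 ± 0.33, and the sodium channel gene SCN3A by 1.99 ± 0.49 (adjusted p = 0.0183 and 0.0277). With vector libraries alone as controls, which leaves 3 controls, none of these 8 genes was called (adjusted p from 0.0863 for SNAP25 to 0.272 for NHLH1). Fold changes there were 3.23 for UNC13A, 2.79 for SNAP25, 3.17 for CHGB, 1.99 for SCG3, 1.44 for NEFM, 1.26 for NHLH1 and 2.06 for SCN3A. SYT4 also lost its call without HD-MB03 (0.148), NHLH1 without D283 (0.0754), and SCN3A without D283 (1.18, 0.139), without D425 (0.13) and after the GC correction (0.0572).

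Of 24 neuronal differentiation genes tested, 7 rose and none fell; adjusted over the list alone, 12 rose and 1 fell. Their median log2 fold change was 1.19, or 0.91 with the 4 genes that had a group at 0 set to their bound. The list stood above the other genes in camera (adjusted p = 7.84e-08), with adjusted p = 0.611 with an estimated correlation. The fry test, which asks whether the genes of the list move on balance and not whether they move more than other genes, gave adjusted p = 0.0493. The 25 synapse and excitability genes had a median of 0.46 (0.30 at the bound), with 6 risen and 1 fallen, or 6 and 2 adjusted over the list alone; camera gave adjusted p = 0.0225, and 0.803 with an estimated correlation. Among them SV2A, a protein of synaptic vesicles, rose by 0.48 ± 0.11 over the lines and stood at -0.04 in D283, while NLGN1, an adhesion protein of the receiving side of the synapse, fell by 1.56 ± 0.37 (adjusted p = 0.0239). Neither was called without D425 (0.21 and -0.72, adjusted p = 0.365 and 0.215) or with vector libraries alone as controls (0.41 and -1.65, adjusted p = 0.159 and 0.176). With vector libraries alone as controls, none of the neuronal genes was called and the median was 0.89. Without HD-MB03, 9 were called and the median was 1.41 (camera adjusted p = 4.09e-14, 0.244 with an estimated correlation).

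**Figure D2:**
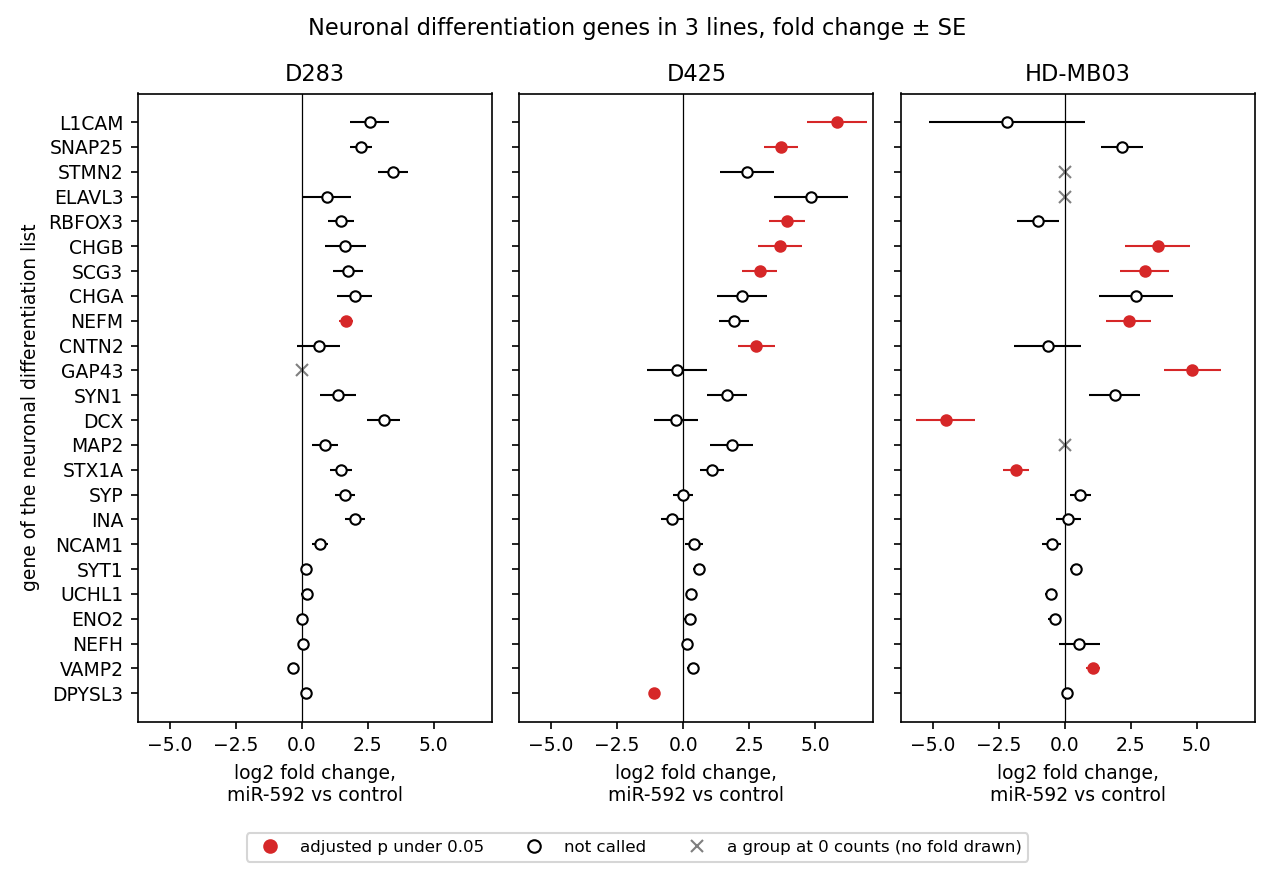
Log2 fold change, miR-592 against control, of each gene of the neuronal differentiation list in D283, D425 and HD-MB03, with its SE as a bar. Genes with a group at 0 counts are drawn as a cross at 0. Of 24 genes, 23 have a fitted value above 0 in D283, 19 in D425 and 15 in HD-MB03. These include GAP43 in D283 and MAP2 and ELAVL3 in HD-MB03, which are drawn at 0. The fitted median in HD-MB03 is 0.49, or 0.11 at the bound.

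Genes that fell over the lines had several functions. IGFBP2, which binds insulin-like growth factors, fell by 2.12 ± 0.23 (adjusted p = 0.00095), and SDC1, a heparan sulfate proteoglycan of the cell surface, fell by 2.00 ± 0.28 (adjusted p = 0.003). SOX11, a transcription factor of neural progenitors and young neurons, fell by 1.63 ± 0.17 (adjusted p = 0.000733), with -3.48 in D425 and -0.28 in D283. PFKP, a phosphofructokinase of glycolysis, fell by 1.40 ± 0.12 (adjusted p = 0.000187). PLK1, a kinase of mitosis, fell by 0.51 ± 0.10 (adjusted p = 0.0125), but stood at 0.08 in D283. The cell cycle list of 31 genes had a median of -0.14, with 2 fallen, or 7 adjusted over the list alone. That list passed camera (adjusted p = 0.0346) but had adjusted p = 0.873 with an estimated correlation. MKI67, the proliferation marker, was not called (0.29 ± 0.14, adjusted p = 0.231), but was called higher with parental libraries alone as controls (0.47, adjusted p = 0.0276) and in D425 fitted on its own (0.63, adjusted p = 0.0278). FDXR, a mitochondrial reductase that p53 induces, fell by 1.03 ± 0.19 (adjusted p = 0.00949). FASN, the fatty acid synthase, fell by 1.12 ± 0.17 (adjusted p = 0.0045), a fall carried by HD-MB03, since the value without that line was -0.06. With vector libraries alone as controls SDC1 (-2.17, adjusted p = 0.0501), PLK1 (-0.37, 0.161), FDXR (-0.87, 0.0646) and FASN (-1.05, 0.108) were not called. PLK1 and FDXR also lost their calls without HD-MB03 (0.141 and 0.109) and after the GC correction (0.0591 and 0.0506).

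MYC, the oncogene amplified or highly expressed in Group 3, had a log2 fold change of -0.57 ± 0.18 (adjusted p = 0.0783; 0.0256 by DESeq2) and was lower on average in each of the 3 lines, at -0.57, -0.76 and -0.38. OTX2, a homeobox factor of Group 3 and Group 4 tumours, had -0.23 ± 0.08 (adjusted p = 0.0804), and was called by DESeq2 (0.0099) and with parental libraries alone as controls (0.0491). NRL, a photoreceptor transcription factor, rose by 0.86 ± 0.24 (adjusted p = 0.0475), a call lost with DESeq2 size factors (0.0505), with vector (0.15) or parental controls alone (0.64, adjusted p = 0.179), without D283 (0.35, adjusted p = 0.343) and without D425 (0.0669). GABRA5, a GABA receptor subunit typical of Group 3, fell by 0.76 ± 0.13 (adjusted p = 0.00767), with -2.22 in D425 and -0.03 in each other line, and was not called without D425 (-0.02, adjusted p = 0.943) or with vector controls alone (0.0857). The 9 Group 4 genes had a median of 0.09 with 1 risen, CBFA2T2, a transcriptional corepressor (0.53 ± 0.12), which was not called without D425 (adjusted p = 0.129) or with vector controls alone (0.186). The 21 Group 3 and photoreceptor genes had a median of 0.22, with 2 risen and 1 fallen, or 3 and 2 adjusted over the list alone. Camera gave adjusted p of 0.7 and 0.305 for these lists. PDLIM3, an actin-binding protein and a marker of the SHH group, rose by 1.44 ± 0.12 (adjusted p = 0.000176), with 1.81 in D283, 2.22 in D425 and 0.28 in HD-MB03. DEPTOR, an inhibitor of mTOR and a proposed miR-592 target, was not called over the lines (-0.32 ± 0.17, adjusted p = 0.29), but was without HD-MB03 (-0.86, adjusted p = 0.0304).

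The series also names mTOR and ERK signalling. DUSP6, a phosphatase that ERK induces and that limits it, rose by 1.68 ± 0.45 over the lines (adjusted p = 0.0399), a call that HD-MB03 carried with a ratio of 19.2 (5.26 to 159). It was lost without that line (0.42, adjusted p = 0.48), with vector (0.29) or parental controls alone (3.43, adjusted p = 0.0625), without D425 (0.0617) and after the GC correction (0.0637). The 18 genes of ERK output had a median of 0.39, with 1 risen and 1 fallen, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.669). ASNS, which makes asparagine and is induced by ATF4 downstream of mTOR, was not called over the lines (0.62 ± 0.27, adjusted p = 0.177) except without D425 (1.51, adjusted p = 0.0257), nor was HMGCS1, an enzyme of sterol synthesis (0.15 ± 0.20, adjusted p = 0.708). The lists of ATF4 and amino acid synthesis (27 genes, 1 fallen), sterol and lipid synthesis (26 genes, 3 fallen), glycolysis and hypoxia (19 genes, 2 fallen) and lysosome and autophagy (25 genes, 1 risen and 2 fallen) had medians of 0.09, -0.07, -0.12 and -0.12. Ribosome biogenesis (19 genes, 1 fallen) and ribosomal proteins and translation (24 genes, 2 fallen) had medians of 0.01 and 0.03. Camera adjusted p for these 6 lists lay between 0.162 and 0.868. MVD and CYP51A1, enzymes of sterol synthesis, and the autophagy kinase ULK1 fell over the lines, but had positive values without HD-MB03, at 0.28, 0.49 and 0.26.

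None of the remaining lists passed camera in the fit of all 3 lines, although more lists passed without HD-MB03, as counted further below. Medians were -0.19 for 8 candidate miR-592 targets, 0.81 for 18 neurogenic transcription factors (0.23 at the bound), -0.12 for 11 SHH and WNT genes, 0.06 for 13 neural progenitor genes, -0.27 for 18 p53 targets and -0.45 for 9 interferon genes. For 12 housekeeping genes the median was -0.06. Median, mean and test differed in sign for SHH and WNT, neural progenitor, ribosome biogenesis and housekeeping genes, and fry gave adjusted p = 0.0392 for SHH and WNT. Glial (5 genes, 0.72), mesenchymal (10 genes, 0.08) and endothelial and blood markers (3 genes, 0.74) had no called member. ETS1, a transcription factor among the candidate targets, fell by 0.83 ± 0.22 over the lines but stood at 0.49 in D283, while WSB1, a ubiquitin ligase subunit in the same list, rose by 0.62 ± 0.13. WSB1 lost its call with vector controls alone (0.37, adjusted p = 0.118), without D425 (0.41, adjusted p = 0.081) and without HD-MB03 (0.53, adjusted p = 0.072). ETS1 lost its own with vector (0.119) or parental controls alone (0.173), without D425 (-0.22, adjusted p = 0.662) and without HD-MB03 (0.105).

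In all, 1305 of 16412 genes were called over the lines, 362 higher and 943 lower. The excess of falls shrank to 238 higher and 275 lower after a correction for GC content, and to 1322 and 1457 with parental libraries alone as controls. Without HD-MB03 it turned, to 431 higher and 327 lower. With vector libraries alone as controls 75 genes were called, and with 1 library left out between 296 and 2199. The HD-MB03 control libraries held 30.9% and 26.4% of reads that did not align, against 4.35% to 8.62% in every other library, and were the shallowest. Since those libraries are the only controls of that line, calls over the lines and in HD-MB03 move with them.

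The comparison within D283 asks for the response of that line. NEFM went from 151 to 488 CPM, a rise of 1.69 ± 0.27 (3 controls, 2 miR-592 libraries; adjusted p = 0.0312). CDK5R2, a neuronal activator of the kinase CDK5, rose by 3.13 ± 0.55 (adjusted p = 0.0471), and TMEM178B, a transmembrane protein, by 3.43 ± 0.49 (adjusted p = 0.0205). POU4F2, a transcription factor of retinal ganglion cells, had a ratio of 32.0 (8.23 to 275). Falls included DMBX1, a homeobox factor of the developing brain, which fell by 1.18 ± 0.18 (adjusted p = 0.0447), and SLC6A15, a transporter of branched amino acids in neurons (adjusted p = 0.0484). With vector libraries alone as controls, NEFM (1.32, adjusted p = 0.13), CDK5R2 (2.38, 0.185), TMEM178B (2.92, 0.141), POU4F2 (3.54, 0.136), DMBX1 (-1.16, 0.0728) and SLC6A15 (-0.87, 0.141) were no longer called, nor were they with D283 fitted on its own (adjusted p between 0.114 and 0.198). DEPTOR went from 90.1 to 35.7 CPM without passing the test (-1.33 ± 0.24, adjusted p = 0.0581), but was called by DESeq2 (0.000271), with no filter (0.0357), with parental libraries alone as controls (0.0126) and after the GC correction (0.0441). STMN2 and DCX, microtubule proteins of growing neurons, stood higher by 3.46 ± 0.58 and 3.10 ± 0.62, also without passing (adjusted p = 0.057 and 0.0694). Both were called by DESeq2 (0.00125 and 0.00391), with no filter (0.0298 and 0.0418) and with parental libraries alone as controls (0.0372 and 0.0295), and STMN2 after the GC correction (0.0441).

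The D283 neuronal differentiation list had a median of 1.49 (1.43 at the bound), with 1 member risen over all genes and 11 adjusted over the list alone. Camera gave adjusted p = 9.5e-13, and adjusted p = 0.0669 with an estimated correlation. The synapse list (median 0.93, 11 risen adjusted over the list alone) and the neurogenic transcription factors (median 1.19, 0.76 at the bound, 4 risen adjusted over the list alone) stood above the other genes too, with adjusted p = 0.0963 and 0.0567 with an estimated correlation. Group 4 genes (0.48), Group 3 and photoreceptor genes (0.09), SHH and WNT genes (0.50) and sterol and lipid genes (0.17) also passed camera, and none did with an estimated correlation (adjusted p = 0.105, 0.382, 0.0669 and 0.889). In all, 29 genes were called, 25 higher and 4 lower, and 324 by DESeq2. No member of the neuronal differentiation list other than NEFM was called over all genes in this line.

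Within D425, the response was broader. RSPO1, a secreted enhancer of WNT signalling, went from 0.30 to 50.2 CPM, a rise of 7.30 ± 0.97 (2 controls, 2 miR-592 libraries; adjusted p = 0.00234). L1CAM, an adhesion protein of axons, rose by 5.84 ± 1.13 (adjusted p = 0.0103), RBFOX3, which encodes the neuronal nuclear antigen, by 3.92 ± 0.68 (adjusted p = 0.00624), and SNAP25 by 3.71 ± 0.63 (adjusted p = 0.00563). Photoreceptor and Group 3 genes fell in part: PDC, a regulator of phototransduction, went from 87.6 to 3.42 CPM (fell by 4.67 ± 0.38, adjusted p = 0.00012), and GABRA5 fell by 2.22 ± 0.25 (adjusted p = 0.000521). OTX2 fell by 0.55 ± 0.14 (adjusted p = 0.0288). ABCA4, a photoreceptor transporter, rose by 2.44 ± 0.51 (adjusted p = 0.0154), so that 2 of the Group 3 and photoreceptor genes rose and 4 fell. SPRY4, a feedback inhibitor that ERK induces, rose by 2.70 ± 0.60 (adjusted p = 0.0191), while DUSP5, a phosphatase of ERK, fell by 1.47 ± 0.40. ETS1 fell by 2.03 ± 0.40 (adjusted p = 0.0108) and FOXO3, a transcription factor with a miR-592 site, by 0.66 ± 0.18 (adjusted p = 0.0441). FOXO3 was not called with DESeq2 size factors (0.0535), with the parental library alone as control (-0.44, adjusted p = 0.15) or with D425 fitted on its own (0.054). With the vector library alone as control RBFOX3 (3.78, adjusted p = 0.0731), SNAP25 (3.52, 0.0693), SPRY4 (2.31, 0.0959) and DUSP5 (-1.32, 0.0611) were not called.

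The D425 neuronal differentiation list had a median of 1.36, with 6 risen and 1 fallen, or 9 and 1 adjusted over the list alone. DPYSL3, a protein of growth cones, was the member that fell, by 1.10 ± 0.17. Camera gave adjusted p = 0.000132, and adjusted p = 0.5 with an estimated correlation. Markers of other cell types had positive medians too: 1.52 for 3 endothelial and blood, 0.40 for 10 mesenchymal and 0.32 for 5 glial markers. Members called higher included KDR of the first list and COL1A1 and LUM of the second. COL1A1 lost its call after the GC correction (adjusted p = 0.0909) and without a filter (0.0524), and LUM by DESeq2 (0.0553). KDR (2.78), COL1A1 (2.46) and LUM (2.90) were not called with the vector library alone as control. COL1A1 (1.345) and LUM (2.34) were not called with the parental library alone either. Of the lists, 5 stood below the other genes in camera, none with an estimated correlation. ATF4 and amino acid synthesis had a median of -0.79 (camera adjusted p = 1.09e-05, 0.5 with an estimated correlation), with MTHFD2, an enzyme of mitochondrial folate metabolism, fallen by 0.79 ± 0.22 (adjusted p = 0.0449; 0.0508 with the parental library alone as control). Ribosomal proteins and translation had a median of -0.32 (0.000132, 0.5), with 1 fallen over all genes and 5 adjusted over the list alone. p53 targets (-0.53; 0.00631, 0.5), cell cycle (-0.29; 0.0211, 0.62) and glycolysis and hypoxia (-0.25; 0.0448, 0.5) lay lower as well. PFKP fell by 2.70 ± 0.22 (adjusted p = 9e-05), and TPX2, a protein of the mitotic spindle, by 0.94 ± 0.20. In all, 799 genes rose and 488 fell; after the GC correction 684 were called higher and 1287 lower, and the lowest count with 1 library left out was 178. MYC and DEPTOR were not called (adjusted p = 0.177 and 0.38), although MYC was with D425 fitted on its own (-0.73, adjusted p = 0.0339).

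Within HD-MB03, FOS, a transcription factor that ERK induces within minutes, had a ratio of 480 (164 to 2328), but lost its call with the vector library alone as control (7.89, adjusted p = 0.0518). EGR1, another such factor, went from 10.4 to 509 CPM, a rise of 5.61 ± 1.49 (2 controls, 2 miR-592 libraries; adjusted p = 0.0126). ASNS went from 54.8 to 488 CPM, a rise of 3.16 ± 0.53 (adjusted p = 0.000899), and CTH, which makes cysteine, rose by 2.84 ± 0.44 (adjusted p = 0.000493). NOTCH1, the receptor that holds progenitors undifferentiated, fell by 3.40 ± 0.35 (adjusted p = 4.67e-05). In D425 NOTCH1 was called in the opposite direction, higher. That call was lost with the vector (1.85) or the parental library (1.72) alone as control. FASN went from 1711 to 181 CPM, fell by 3.24 ± 0.33 (adjusted p = 4.35e-05), and ULK1 fell by 3.18 ± 0.25 (adjusted p = 1.36e-05). GAP43, a protein of growth cones, had a ratio of 29.6 (5.25 to 1176), whereas DCX fell by 4.50 ± 1.13 (adjusted p = 0.00913), with 19 counts over the controls and 5 over the miR-592 libraries. DCX had -1.28 (adjusted p = 0.763) with the vector library alone as control, and adjusted p = 0.0697 after thinning. CCND1, a cyclin of the G1 phase, fell by 3.14 ± 0.71, and with about the same fold had adjusted p = 0.0526 with the vector library alone as control. MYC was not called (adjusted p = 0.412).

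The HD-MB03 neuronal differentiation list did not pass (median 0.49, 0.11 at the bound, camera adjusted p = 0.65), with 5 risen and 2 fallen. ATF4 and amino acid synthesis had 11 of 27 genes risen and 1 fallen, or 15 and 2 adjusted over the list alone, and a median of 0.91 (camera adjusted p = 0.0126, 0.965 with an estimated correlation). Of 24 ribosomal protein and translation genes, 15 rose and 3 fell, or 18 and 4 adjusted over the list alone, with a median of 0.53 (camera adjusted p = 0.00746, 0.965 with an estimated correlation). RPL23, of the large subunit, rose by 1.17 ± 0.18, and EEF2, the elongation factor, fell by 1.09, a value of 0.08 after correction for GC content. Of the sterol and lipid genes 1 rose and 7 fell. The ERK output list, which holds FOS and EGR1, had a median of 0.06 (camera adjusted p = 0.945). The count of calls, 5232 of 16412 (2496 higher, 2736 lower), went with the GC content of the genes: the rank correlation of fold change with GC content across genes was -0.604, and genes are not independent replicates. A correction for GC content left 2315 calls (1672 higher, 643 lower), and 1575 genes were called both ways.

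The test of a difference between lines asks whether the lines responded alike. It called 5234 genes in edgeR, and 593 when HD-MB03 was left out. ASNS had log2 fold changes of -0.13 in D283, -1.15 in D425 and 3.16 in HD-MB03 (adjusted p of the difference = 0.00208). DEPTOR had -1.33, -0.39 and 0.78 (adjusted p = 0.00841). Across genes, Pearson's r of the fold changes was 0.0441 between D283 and D425, -0.053 between D283 and HD-MB03 and -0.102 between D425 and HD-MB03, with rank correlations of 0.012, -0.143 and -0.18. Of the genes called in D283 and in D425, 10 were higher in both, against 1.22 if the calls were independent. Between D425 and HD-MB03, 376 genes were called in opposite directions against 207, 27 were higher in both against 122, and 39 were lower in both against 81.4. After the GC correction 333 were opposite against 162 and 28 higher in both against 71.5, but 67 were lower in both against 51.8, with a rank correlation of -0.068.

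Whether the vector itself alters expression was read from vector against parental cells. No gene was called in edgeR, where 1058 of 15508 had an unadjusted p under 0.05, and DESeq2 called 43. EGR1 stood at 173 CPM in D425 parental cells and 3.76 in D425 vector cells, and FOS at 129 and 2.94 CPM, with 1 library each. The neuronal differentiation list, here of 20 genes, had a median of 0.40 in vector over parental cells (camera adjusted p = 0.00115, 0.773 with an estimated correlation). Glycolysis and hypoxia genes (-0.25) and cell cycle genes (-0.17) lay lower, with adjusted p = 0.367 and 0.854 with an estimated correlation. No list of another cell type passed.

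If miR-592 represses its targets, genes with a site for its seed should lie lower than genes without one. In D425 the 1636 genes with a 7-mer site had a median log2 fold change lower than that of the 11635 genes without one, by a difference of -0.07 against a permuted mean of -0.03 (permutation p = 0.00353, adjusted 0.0141). With an 8-mer site the difference was -0.15 against a permuted mean of -0.03 (permutation p = 0.0001, the smallest that 10000 permutations can give; adjusted 0.0004). After the GC correction the 7-mer difference in D425 was -0.01 against a permuted mean of 0.02 (adjusted p = 0.01). D283 gave -0.04 against -0.02 (permutation p = 0.0326, adjusted 0.0652), all lines 0.04 against 0.05 (0.491, adjusted 0.654) and HD-MB03 0.25 against 0.24 (0.692). After the GC correction all lines gave -0.01 against 0.003 (permutation p = 0.025, adjusted 0.05). Among the 420 7-mers of the same bases, TGACACA ranked 47 from the lowest in D425, 71 in D283, 91 over the lines and 138 in HD-MB03. DEPTOR, FOXO3 and TGFB2, a growth factor, each held 1 7-mer, also an 8-mer. DEK, another candidate target, held 2 7-mers, 1 of them an 8-mer, and IGF1R held 1 7-mer. DEK was called higher in HD-MB03, against the direction of repression. That call was lost after the GC correction (0.66, edgeR adjusted p = 0.0933) and with the line fitted on its own (0.94, edgeR adjusted p = 0.132). ETS1, SPRY2 and WSB1 held no site.

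The drug comparisons ask which changes depend on mTOR or on MEK and ERK. Before them stands a feature of 2 of their libraries. MUC16, a cell surface mucin, stood at 470.5 CPM in untreated D283 and 0.099 in untreated D425, yet at 193 and 643.5 CPM in D425 miR-592 cells given rapamycin and U0126. PEG10, an imprinted gene of retroviral origin, stood at 466 CPM in untreated D425 and at 133 and 71.7 in those libraries. The 42 genes restricted to D283 stood there at a median of 0.456 and 0.553 of their D283 level, and all 42 were detected. The 38 genes restricted to D425 stood at 0.388 and 0.400 of their D425 level. In D425 vector cells given the same drugs, the D283 genes stood at 0 and 0.0085 and the D425 genes at 0.762 and 0.765. Every drug value below that uses the D425 miR-592 population carries this feature.

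**Figure D3:**
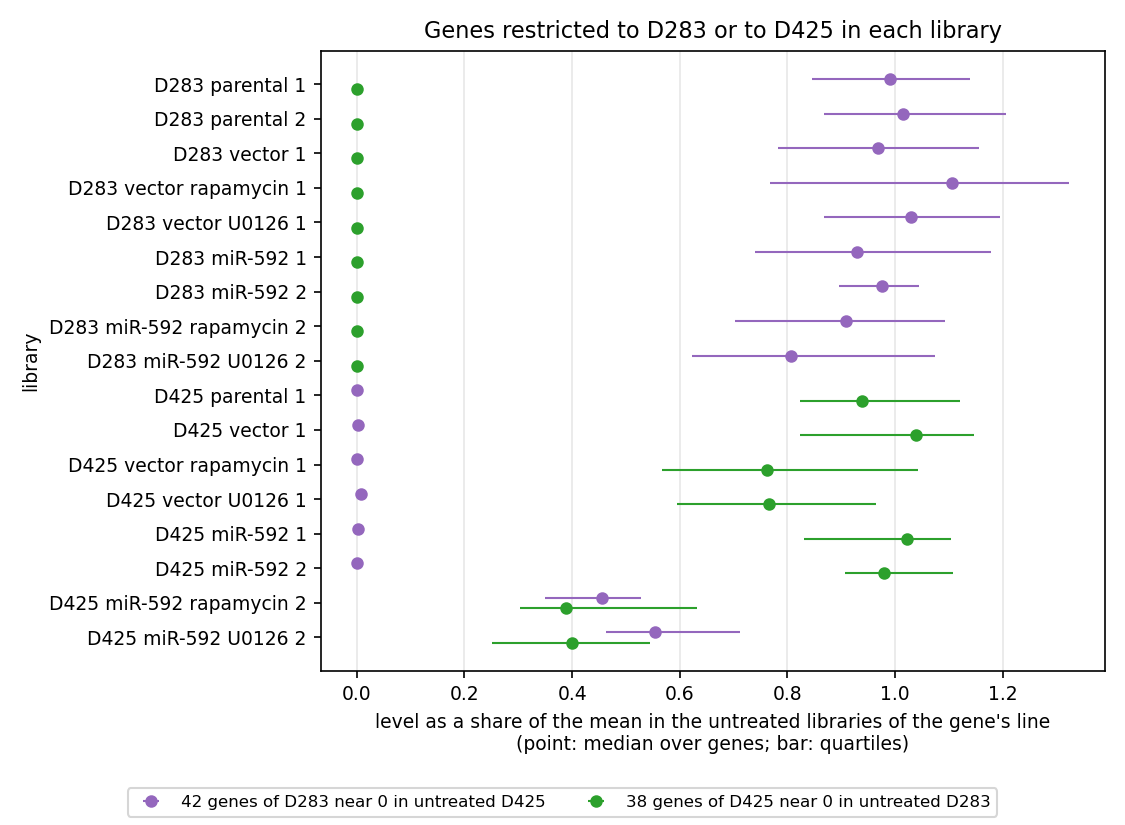
Level of the genes restricted to D283 (42) and to D425 (38), as a share of their level in their own untreated line. Every D283 and D425 library is drawn, with the median over genes as a point and the quartiles as a bar. The D425 miR-592 libraries given drugs hold both kinds at medians between 0.388 and 0.553. The D425 vector libraries given drugs hold the D283 kind at 0.0085 or less.

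Rapamycin against no drug asks what mTOR inhibition does. By the library numbers in the labels, the drug libraries form a series of their own. They were also shallower than the untreated libraries of the same populations. A batch and the drug therefore cannot be separated in this comparison. FOS stood higher by 4.19 ± 0.90 and EGR1 by 3.23 ± 0.74, in 4 of 4 populations each, without passing the test (4 populations; edgeR adjusted p = 0.559 for both; EGR1 had 0.000364 by DESeq2). Rapamycin libraries held 30.7 to 138 CPM of EGR1 and 35.6 to 106 of FOS. Untreated libraries outside this comparison reached such levels: D425 parental held 173 and 129 CPM, and D283 miR-592 1 held 93.6 and 122. The remaining untreated libraries of these lines outside it held 4.73 to 24.8 CPM of EGR1 and 1.18 to 16.3 of FOS. Both rises therefore depend on the untreated library compared. SLC1A3, a glutamate transporter of glia, was lower in 4 of 4 (-1.06 ± 0.17, adjusted p = 0.559). NES, an intermediate filament of progenitors, stood higher (0.80 ± 0.15, adjusted p = 0.559). No gene of 14868 was called in edgeR; 947 had an unadjusted p under 0.05, and DESeq2 called 32. By camera, 8 lists passed. ERK output had a median of 0.34 (adjusted p = 0.00213, 3 risen adjusted over the list alone), cell cycle 0.33 (2.02e-08), p53 targets 0.29, glycolysis and hypoxia 0.13, neural progenitor genes 0.14 (2 risen adjusted over the list alone), ATF4 and amino acid synthesis -0.25 (0.00276), sterol and lipid synthesis -0.19, and endothelial and blood markers -0.996 over 3 genes. None passed with an estimated correlation: adjusted p = 0.528 for ERK output and 0.662 for cell cycle, and at most 0.799 for the others. Without the D425 miR-592 population, ERK output (0.48), cell cycle (0.23) and ATF4 (-0.35) still passed camera with the preset correlation.

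U0126 against no drug asks what MEK inhibition does. As for rapamycin, the drug libraries form a shallower series of their own, so a batch and the drug cannot be separated. A shift shared by both drugs may be either. EGR1, a direct readout of ERK, had -1.89 ± 0.81 (adjusted p = 0.701) and was lower in 4 of 4 populations. In D283 it went from 3.40 to 3.12 CPM in vector cells, almost unchanged, and from 19.2 to 1.69 in miR-592 cells. In D425 it went from 3.76 to 0.714 in vector and from 6.18 to 2.07 in miR-592 cells. The U0126 libraries held 18, 10, 3 and 9 counts of EGR1 in that order, so the direction rests in part on few reads. FOS, which ERK also induces, did not share that direction (2.26 ± 0.94, adjusted p = 0.701), with 5.36 and 2.71 in the D283 and D425 vector populations and -0.55 and 0.22 in the miR-592 ones. ABCA4 was lower in 4 of 4 (-1.16 ± 0.22, adjusted p = 0.458), as was SLC1A3 (-0.98 ± 0.17, adjusted p = 0.457). DKC1, a pseudouridine synthase of ribosome assembly, was also lower in 4 of 4 (-0.52 ± 0.15). No gene was called in edgeR; 1040 of 14868 had an unadjusted p under 0.05, and DESeq2 called 44. Ribosome biogenesis genes had a median of -0.35 (camera adjusted p = 6.63e-09, 0.527 with an estimated correlation), Group 3 and photoreceptor genes -0.59 (4.4e-06, 0.446), and ribosomal proteins and translation -0.20 (0.000315, 0.82). Cell cycle genes had 0.24 and 3 endothelial and blood markers -0.70, with 0.82 and 0.527 with an estimated correlation. Without the D425 miR-592 population the Group 3 and ribosome biogenesis lists kept negative medians, -0.65 and -0.28.

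The comparison of rapamycin with U0126 asks how the inhibitors differ, and it contrasts only drug libraries, whose library numbers in the labels form a series apart from the untreated ones. EGR1 stood higher with rapamycin by 5.12 ± 0.81, in 4 of 4 populations (4 populations; edgeR adjusted p = 1, DESeq2 2.59e-11). DUSP6, SPRY4 and DUSP5, each induced by ERK, stood higher by 1.38 ± 0.50, 1.58 ± 0.64 and 0.88 ± 0.32, in 4 of 4 populations each. Counts of DUSP6 with rapamycin and U0126 were 13 and 2 in D283 vector and 8 and 7 in D283 miR-592 cells. In D425 they were 8 and 5 in vector and 21 and 7 in miR-592 cells. SPRY4 had 6 and 1 counts in D425 vector cells and at least 10 in every other drug library. The directions thus rest in part on few reads. NRL stood higher by 1.29 ± 0.39 and SQSTM1, an autophagy receptor, lower (-0.59 ± 0.26), each in 4 of 4. No gene was called in edgeR, with 182 at an unadjusted p under 0.05 and 2 by DESeq2. The 17 ERK output genes had a median of 0.50 (camera adjusted p = 1.78e-11, 0.103 with an estimated correlation), with 1 risen adjusted over the list alone. In vector populations alone their median was also 0.50 (camera adjusted p = 2.12e-08, 0.922 with an estimated correlation). Group 3 and photoreceptor genes (0.41, adjusted p = 1.64e-08, 0.103 with an estimated correlation) and ribosome biogenesis (0.26, adjusted p = 2.82e-09, 0.345) stood higher with rapamycin as well. Ribosomal, glycolysis, p53 and cell cycle lists lay higher by 0.14 to 0.18, and ATF4 and sterol lists lower, at -0.19 and -0.11; none passed with an estimated correlation.

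**Figure D4:**
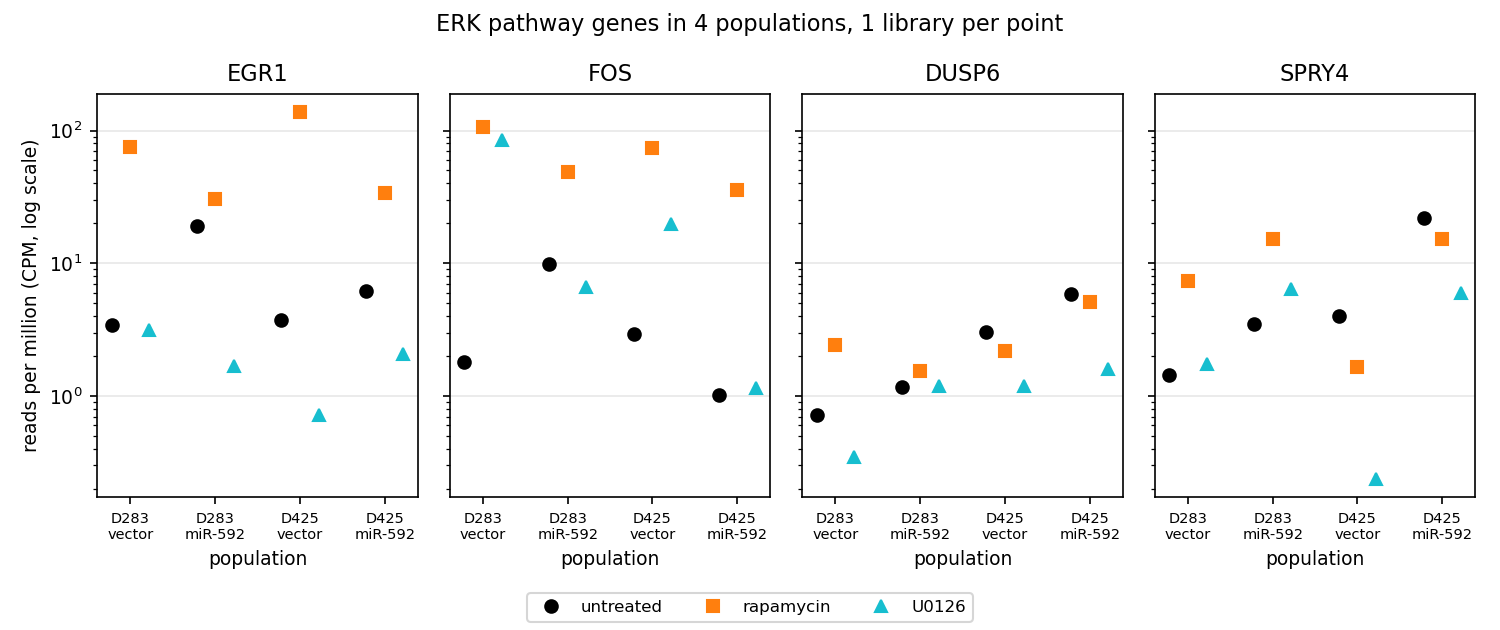
Level of EGR1, FOS, DUSP6 and SPRY4, in CPM on a log axis, without drug, with rapamycin and with U0126. Each point is 1 library of the 4 populations. DUSP6 and SPRY4 rest on few reads in some libraries. For each gene, all 4 populations sit higher with rapamycin than with U0126.

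Whether drugs act differently once miR-592 is present was tested as a difference of responses. For U0126, 2 genes were called, with 1458 at an unadjusted p under 0.05 and 73 by DESeq2. GPNMB, a glycoprotein of lysosomes, responded 4.26 ± 0.38 higher on the log2 scale in miR-592 than in vector cells (adjusted p = 0.0251), with 2.78 and 2.34 in the D283 and D425 miR-592 populations and -1.65 and -1.44 in the vector populations. STC1, a secreted glycoprotein hormone, responded -2.88 ± 0.25, with -2.02 and -2.15 in miR-592 populations and 0.75 and 0.72 in vector populations. Without the D425 miR-592 population no gene was called (GPNMB 4.46, adjusted p = 0.221; STC1 -2.85, 0.276). Neither gene was called when any of 10 of the 12 libraries was left out. For rapamycin no gene was called in edgeR, with 1193 at an unadjusted p under 0.05 and 26 by DESeq2. DEPTOR had differences of 1.77 ± 0.43 for rapamycin and 1.97 ± 0.44 for U0126 (adjusted p = 0.556 and 0.411; 0.0432 for U0126 by DESeq2). Interferon genes had list medians of 2.26 and 1.96 and candidate miR-592 targets 0.98 and 1.07, all past camera, with adjusted p = 0.369 for rapamycin and 0.45 for U0126 with an estimated correlation for both lists. These medians include the D425 miR-592 libraries that hold D283-restricted genes.

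Within each drug state, miR-592 was set against vector cells of D283 and D425. No gene was called in edgeR without drug, with rapamycin or with U0126, where 253, 1195 and 1335 genes had an unadjusted p under 0.05 and DESeq2 called 6, 77 and 197. Without drug, the neuronal differentiation list had a median of 0.53 (camera adjusted p = 8.09e-06, 0.537 with an estimated correlation), and 7 candidate targets a median of -0.56 (adjusted p = 0.0018, 0.537). With rapamycin the neuronal list had a median of 0.17 and a mean of -0.32 (camera adjusted p = 0.86). A difference between drug states in this list was tested as a difference of responses: its median was -0.86 for rapamycin (camera adjusted p = 0.00232, 0.369 with an estimated correlation) and -0.64 for U0126 (adjusted p = 0.0285, 0.474), with the same 2 libraries included.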

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

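The tests of GC content, of depth by thinning and of the batch in HD-MB03 were chosen only after the data were seen. So were the GC and split tests of the neuronal list, and the limit for its median with vector controls alone. The tests of the D425 miR-592 libraries given drugs address a feature seen in the data, so they were not planned before it. The other tests here were chosen before.

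Results stood out here because the response to miR-592 differed between lines by a test of the difference itself. This test called 5234 genes, and among the genes named by rule 113 differed between lines. In addition, 376 genes were called in D425 and in HD-MB03 with opposite signs. ASNS differed with adjusted p = 0.00208, at -0.13 in D283, -1.15 in D425 and 3.16 in HD-MB03. DCX differed with adjusted p = 0.00239, at 3.10, -0.28 and -4.50, although its HD-MB03 value was -1.28 (adjusted p = 0.763) with the vector library alone as control. DEPTOR differed with adjusted p = 0.00841. Among genes that ERK induces, DUSP6 differed with adjusted p = 0.0452, EGR1 with adjusted p = 0.00907 and SPRY4 with adjusted p = 0.0117. EGR1 stood at 1.99, -3.95 and 5.61, and SPRY4 at -0.35, 2.70 and -1.13. The D425 value of EGR1 rested on the parental library, at 173 CPM against 3.76 in vector cells and 4.73 and 6.18 in miR-592 cells, so its direction turned with the control. Its D283 value rested largely on miR-592 1, at 93.6 CPM against 19.2 in miR-592 2. The D283 controls held 14.9, 24.8 and 3.40 CPM. The U0126 response differed between miR-592 and vector cells for GPNMB, by 4.26 on the log2 scale, and for STC1, by -2.88. No group had enough libraries for a test of single outlying libraries.

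Other splits of the same libraries were counted for each of these comparisons. For the difference between lines, 1 of 60 splits drawn from 360 possible, the real one, gave as many calls, with 5234 against 4682 at the highest of the others. That share lies under 0.05, but the share among all 360 splits is not settled. The splits also did not hold the grouping of HD-MB03 fixed. Chance is therefore not excluded, nor is a structure of the samples. The libraries of HD-MB03, described next, may account for much of that count. For miR-592 over the lines, 6 of 60 splits gave as many as 1305 calls, with 3330 at the highest of the others, so chance was not excluded. All 5 other splits that did so put the HD-MB03 controls apart from the HD-MB03 miR-592 libraries. Among the 18 splits that do this the highest count was 3330, and among the rest it was 2. Those 18 splits keep the real grouping of HD-MB03 or its mirror. An effect of miR-592 and a structure of the samples in that line would both give this pattern, so the splits cannot tell them apart. For vector against parental cells, 12 splits exist, and all 12 gave 0 calls, real and highest other alike. For rapamycin, U0126 and rapamycin against U0126, 8 exist each, with 0 calls in the real split and 0 at the highest other. These are too few for a share under 0.05.

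D425 miR-592 libraries given drugs held genes that D425 lacks and D283 expresses. A label swapped with a D283 library is excluded, since genes restricted to D425 kept a median share of at least 0.388 of their D425 level. A response of D425 cells to the drugs as such is excluded, since the D283-restricted genes stood at no more than 0.0085 in D425 vector cells given the same drugs. A mixture with D283 cells or RNA remains, because the shares of the 2 kinds of gene added up to 0.844 with rapamycin and 0.954 with U0126, where a mixture predicts a sum near 1. A response that needs both drug and miR-592 may still account for part, and no library tests it apart.

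HD-MB03 gave the highest number of calls of any line. Depth alone is excluded, because 4343 calls were left of 5232 after the miR-592 libraries were thinned to the depth of the deeper control. A GC-dependent bias between libraries may account for much of the number, since 44.2% of the count was left after a correction, and the median size of the called changes went from 1.14 to 0.56. Both controls held at least 26.4% of reads that did not align, and no other control of the line exists, so a batch of sequencing or RNA cannot be told apart from the effect of miR-592 in this line. A response to miR-592 stays open too.

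The neuronal differentiation list rose with miR-592 over the lines in camera, with adjusted p = 0.611 with an estimated correlation. A difference between parental and vector cells as the whole cause is excluded, because its median was still 0.89 with vector libraries alone as controls, against 1.19. GC content is excluded in the same way, with a median of 1.34 after correction. Of 60 splits, 2 had a median as far from 0, the real one included, and the highest of the others was 1.35. That share lies under the limit of 0.05, but the 60 were drawn from 360 possible splits, so the share among all of them is not settled. In addition, 1 other split had a median further from 0 than the real one, and the splits did not hold the grouping of HD-MB03 fixed. Chance is therefore not excluded. An effect of miR-592 on neuronal genes is a hypothesis that remains in line with the median of 0.89, while a difference in culture or batch between populations was not tested.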

How the results depend on the processing

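The GC correction, the thinning, the omission of the D425 miR-592 population or its drug libraries, the gene lists without HD-MB03 or in vector populations only, the difference between lines without HD-MB03, D283 parental cells alone without the number, and every alternative for miR-592 against vector within drug states were chosen only after the data were seen; the others were chosen before the data were examined.

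With DESeq2 size factors, counts of calls stayed within 1.5 times of those reported in every comparison. Seed site tests kept their side of the threshold under every alternative run, except that the test over the lines came to the threshold itself after the GC correction. Its permutation p was then 0.025, adjusted 0.05, against adjusted 0.654 in the main test. The differences over the lines and in HD-MB03 turned negative after that correction, at -0.01 and -0.02. Pearson correlations between lines moved by less than 0.1, and the rank correlation of D425 with HD-MB03 from -0.18 to -0.068 after the GC correction. Without a filter the counts that moved were D283, 53, and miR-592 against vector without drug, 1. The DESeq2 test gave 2186 calls over the lines and 324 in D283, 43 for vector against parental, 32 for rapamycin, 44 for U0126 and 2 for rapamycin against U0126. It gave 26 and 73 for the difference in rapamycin and U0126 response, and 6, 77 and 197 for miR-592 against vector without drug, with rapamycin and with U0126. The cause was not tested.

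With vector controls alone the counts were 75 over the lines, 55 in D283 and 3245 in HD-MB03, and with parental controls alone 2779 over the lines and 125 in D283. The cause was not tested; vector controls alone leave 3 control libraries. With each line fitted on its own, D283 gave 3, D425 2471 and HD-MB03 2777 calls, where each line's own spread replaces the shared one. Leaving out D283 gave 2210 calls over the lines, and leaving out HD-MB03 gave 758, with 593 for the difference between lines. After the GC correction the counts were 513 over the lines, 45 in D283, 1971 in D425, 2315 in HD-MB03 and 3300 for the difference between lines.

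The labels number parental and miR-592 libraries of D283 alike. Across genes, the difference between numbers 1 and 2 in parental cells had a correlation of -0.0223 with that in miR-592 cells, so the libraries share only a number. With the number as a replicate block, 1 gene was called in D283, and without it, on the same 4 libraries, 6.

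Over the lines the count ranged from 296 to 2199 as each library was left out. It was 296 without D425 miR-592 replicate 1, 344 without D425 miR-592 2, 378 without HD-MB03 parental, 479 without D283 miR-592 1, 620 without D283 miR-592 2, 627 without HD-MB03 miR-592 2, 747 without D425 parental, 866 without D425 vector and 2199 without HD-MB03 vector. D283 ranged from 9 (without parental 2) to 160 (without vector), with 10 without parental 1, 10 without miR-592 1 and 75 without miR-592 2. D425 ranged from 178 (without miR-592 2) to 760 (without vector), with 196 without miR-592 1 and 357 without parental. HD-MB03 ranged from 2987 (without parental) to 5486, and the difference between lines from 3735 to 5712. A lone library left in a group is assumed to vary like the other groups.

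Vector against parental ranged from 0 to 1, with 1 without D425 parental and 1 without D425 vector. Rapamycin ranged from 0 to 2 (without D425 miR-592 2). The difference in rapamycin response ranged from 0 to 880 (without D283 miR-592 2; 15 without D425 miR-592 2). The difference in U0126 response ranged from 0 to 1022 (without D283 miR-592 2; 19 without D425 miR-592 2), with 0 without each of the other 10 libraries, so GPNMB and STC1 were called only in some of these fits. U0126, rapamycin against U0126, and miR-592 against vector in each drug state stayed at 0 to 0 in edgeR; their unadjusted counts are in the report.

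Without the D425 miR-592 population the difference in U0126 response gave 0 calls, with GPNMB at 4.46 and STC1 at -2.85, and without its 2 drug libraries miR-592 against vector gave 1, 2 and 2 without drug, with rapamycin and with U0126.

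Of the lists for miR-592 over the lines, 3 passed camera; 0 did with an estimated correlation and 11 without HD-MB03. For rapamycin 8 passed, against 0 with an estimated correlation, 0 in fry and 3 without the D425 miR-592 population. For U0126 5 passed, against 0 with an estimated correlation, 0 in fry and 8 in vector populations only. The cause was not tested beyond the correlation between genes that those tests allow for.

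Named genes that reversed without HD-MB03 were CYP51A1 (0.49), MYBBP1A (0.0704), MVD (0.28) and ULK1 (0.26). After the GC correction in HD-MB03, CTSA (0.0303), GRWD1 (0.14), RPL13A (0.0907), UNCX (0.85), MCM7 (0.0144), EEF2 (0.0842), PYCR1 (0.25) and IRF7 (0.00577) reversed. The cause was not tested. Of 1425 other values for the named genes reported here, over the lines, 1011 gave the same verdict, 398 lost the call and 12 gained one. In D283 the numbers were 233, 53 and 17 of 303, in D425 496, 177 and 6 of 679, and in HD-MB03 827, 105 and 3 of 943. For rapamycin 3 of 287 gained a call, for U0126 1, and for rapamycin against U0126 1; none was lost. For the difference in response, 4 of 224 gained one for rapamycin, and 22 of 256 lost and 3 gained one for U0126.

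Depth limits low genes in HD-MB03 controls, where 3 counts over the group correspond to 0.759 CPM. Simulated changes of 1 on the log2 scale were mostly missed in D425, with 18% recovered. Every alternative listed before the data were examined was run.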

Other observations

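MIR592 was always to be named. GPNMB and STC1 were named because their test was passed. No test was added for them.

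MIR592 had fewer reads in miR-592 cells given drugs than in the untreated cells of the same population. The log2 change was -1.67 ± 0.32 with rapamycin and -1.49 ± 0.32 with U0126, neither of which passed the adjustment in edgeR (adjusted p = 0.559 and 0.53). Library numbers in the labels put the drug libraries in a series of their own, so a batch and the drugs cannot be separated here, and D425 miR-592 libraries given drugs also hold D283-restricted genes.

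GPNMB stood at 31.9 CPM in untreated D283 vector cells and 9.88 with U0126, and at 9.82 and 68.5 in D283 miR-592 cells. In D425 vector cells it stood at 5.32 and 1.67, and in D425 miR-592 cells at 3.95 and 19.8. STC1 stood at 15.3 and 25.8 CPM in D283 vector cells and at 15.5 and 3.56 in D283 miR-592 cells. D425 vector cells held 92.8 and 145 CPM of it, and D425 miR-592 cells 216 and 45.0. With rapamycin the values went the same way: GPNMB stood at 12.8 and 2.46 CPM in D283 and D425 vector cells and at 51.0 and 20.3 in miR-592 cells, and STC1 at 24.4 and 144 against 7.35 and 88.2. Both responses were taken against the same untreated libraries, so these values are no separate evidence, and no gene was called for rapamycin. In D283 miR-592 cells given drugs, the genes restricted to D425 stood at a median share of 0 of their D425 level, and both genes moved there in the same directions as in D425. A mixture with D283 miR-592 cells would itself move both genes in these directions in D425. With U0126 those cells held 68.5 CPM of GPNMB and 3.56 of STC1, against 3.95 and 216 in untreated D425 miR-592 cells. The D425 directions are thus no separate evidence.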
